A study of Dictyostelium discoideum with 8 samples.

How the data were processed

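Total RNA from 8 samples of Dictyostelium discoideum was taken with Trizol, poly(A) RNA was selected and Illumina TruSeq libraries were made with PCR enrichment, per the labels' protocols, and sequenced on a MiSeq, per the series' design text. TopHat, Cufflinks 2.2.1 and Cuffdiff are named in the submitters' processing notes. The roles of these tools, the genome build, the annotation, the library scaling and any use of strand are not given in the sources used here. The samples were grouped by the genotype and treatment in GEO's labels into wild type, wild type with tunicamycin, ireA mutant and ireA mutant with tunicamycin, with 2 samples in each. The untreated samples are labelled as having no treatment, while the protocol names DMSO for them. The labels do not say whether the samples of a group came from separate cultures, so that the authors' p-values may rest on technical spread.

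The deposited file is 1 table of 10682 rows in the layout of Cuffdiff's gene comparison output, per the file headers. Each row is a locus in 1 of 6 comparisons between groups, with the authors' value for each group, their log2 fold change, a test statistic (a score), a p-value and a q-value. All 10682 rows carry status OK and are marked significant, with the largest q-value at 0.0499. The authors' group values are read as FPKM, the unit Cuffdiff writes, although the headers say only "value". The deposited log2 fold change equals log2 of the ratio of the group values within 1.50e-05, with no pseudocount. In 207 rows 1 group is listed at 0. The table has 0 columns of replicate values, so the tests on replicates planned before the data were examined (limma or a count model) could not be run, and the authors' own comparison was used as planned for that case. Depth per library is unknown, no interval or detection limit is given, and no fold is given against a value of 0. The q-values fit an adjustment over 58907 tests in all 6 comparisons together, or about 9818 loci per comparison.

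A group's value for a locus is known where any row with that group lists it, and 0 loci had values that differed between rows. This gave 4124 loci, 2537 of them with all 4 values. Missing values belong to loci that passed in no comparison with that group. The table names 4182 genes, of which 3896 matched a symbol or locus tag in NCBI's table for assembly dicty_2.7, used for names only. 78 loci join more than 1 gene, and 0.693% of rows carry the name 0 in place of a gene and were counted as loci but not named. Locus positions are those of the file with 1 added to the start: among 3769 single-gene loci matched to the reference table, 3074 then had the same start and end. They are given on the file's sequence IDs.

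Calls are loci with q under 0.05 in the authors' table. Log changes computed here used log2 of FPKM plus 1, which understates the change of low genes. The rule for named genes was fixed beforehand: ireA, then in each of the 4 main comparisons the 10 genes with a symbol and the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 FPKM, the 10 largest differences of responses of each sign among genes called in at least 1 genotype, and up to 4 called members of each list by size of change. A few other members are named only as the parts of a small count, and the genes grp94, iliD and the dng1 and iliB locus are given further values outside the comparison that named them, and pdiA, atp7a, atp9b, spt16 and spt4 are named as limits of their lists. Those were chosen after the values were seen. Some genes that the rule takes are not reported here. The 2 crossed comparisons, which change genotype and treatment together, served to recover group values and are not reported.

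21 gene lists were fixed by symbol patterns: ER chaperones, ER-associated degradation, N-glycosylation, ER translocation, ER-Golgi transport, autophagy, proteasome, cytosolic ribosomal proteins, cytosolic chaperones, tRNA synthetases, bZIP factors with eIF2-alpha kinases, redox, DNA replication and mitosis, early development, late development, lysosomal hydrolases, V-ATPase, actin and actin-binding proteins, lipid and sterol synthesis, polyketide synthases and mitochondrial respiration. Patterns for product descriptions were also fixed but not used here. Some genes sit in more than 1 list. For lists with at least 3 members, the median change was placed among 10000 random lists of the same size, drawn from listed loci in 10 bins of mean FPKM. This describes these groups and is not a test across replicates. On simulated data for 4124 loci, 6% of 100 lists of 20 loci with no shift fell outside the central 95%, 36% with a shift of 0.5 and 94% with a shift of 1 in log2. The simulated loci all had values and normally distributed changes. The real random lists were drawn from loci called in some comparison, and many fixed lists had fewer members with values. These shares therefore do not give the power for the lists here, and a median inside the central 95% does not show that a list was unchanged.

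Overlaps of calls were set beside the number from independent lists, and, where comparisons shared libraries, beside simulated loci with no effect. Alternatives fixed before the data were examined were q under 0.01, a change of at least 2-fold, at least 1 or 10 FPKM in 1 of the groups, pseudocounts of 0.1 and 5, unmatched random lists and list members with a mean of at least 10 FPKM. Rows naming exactly 1 gene, centring on the median of loci with all 4 values, and lists without members that a symbol pattern took from other functions (pdiA from the ER chaperones, atp7a and atp9b from respiration, spt16 and spt4 from the lipid list) were added after seeing the data. The z-test of the difference of responses, also added then, took the standard error of each log2 fold change as the change divided by the authors' statistic, with adjustment by Benjamini-Hochberg over 397 loci. The statistic's normal p was above the listed p in 75.2% of 10475 rows. In simulated loci called in both genotypes, p was under 0.05 in 1.54% of 83096 with equal responses and in 44.9% of 126813 with a log2 difference of 2. With a log2 difference of 1 it was under 0.05 in 9.76%. For q under 0.05, the threshold used in the results, the shares were 0.00121% with equal responses, 0.0682% with a difference of 1 and 24.5% with 2, so most such differences would be missed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.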

Results

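Poly(A) RNA was sequenced from axenically growing Dictyostelium discoideum, a social amoeba, in a strain labelled wild type (AX4 background) and in a strain labelled as an ireA mutant. The ireA gene encodes the Dictyostelium form of IRE1, a transmembrane kinase and endoribonuclease that senses unfolded protein in the endoplasmic reticulum (ER). Cells were kept for 16 h at 1e+06 cells per ml with 2 µg/ml tunicamycin, which blocks the first step of N-linked glycosylation, or with the solvent DMSO, per the labels' protocols. The 8 samples formed 4 groups of 2. The authors' deposited table gave 1 expression value per gene locus and group, read here as FPKM, and held 0 replicate values, so that no SD is given with any value, each of which stands for 2 samples, and the depth of each library is unknown. Every group value, log2 fold change, q-value and call below comes from that table, and a locus is said to have risen, fallen or been called where the authors' own comparison gave q under 0.05. Folds are ratios of the authors' group values. Gene lists were fixed before the data were examined, and "listed" members are those called in at least 1 of the table's 6 group comparisons. A member outside the table passed in none of them, and its value is not known here. Among genes named by NCBI the patterns match 19 autophagy, 27 ER-Golgi transport, 14 ER translocation, 42 proteasome, 46 respiration and 40 polyketide synthase genes. They also match 81 ribosomal protein genes, 56 genes of replication and mitosis and 83 of actin and actin-binding proteins. A count out of listed members is therefore not a share of the whole family.

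The ireA locus itself (sequence DDB0232428, positions 495059 to 498317) was examined first. In the authors' deposited table it stood at 16.1 FPKM in untreated wild type, 55.3 with tunicamycin, 10.6 in the untreated mutant and 56.2 in the mutant with tunicamycin. It rose with tunicamycin in wild type (log2 fold change 1.78, q = 0.00239) and in the mutant (2.40, q = 0.000726), and was not called between the genotypes in either state. A disruption can leave reads from the rest of a gene, and which part of ireA was disrupted is not given in the sources used here. The value per locus therefore does not check the genotype of any library, and the groups are named throughout as their labels name them.

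The first comparison asked which transcripts tunicamycin changed in wild type. Several genes of COPII transport, ER folding and ER-associated degradation rose. sarB, a Sar1-type GTPase of the COPII vesicle coat (DDB0232430, positions 934441 to 935515), rose 9.35-fold from 49.5 to 462 FPKM, and the COPII coat genes sec23, sec24l and sec24 rose 3.95-, 2.67- and 2.30-fold in the authors' deposited table. The ER co-chaperone dnajc3 rose 3.68-fold (q = 0.000726), the protein disulfide isomerase pdi1 rose 3.13-fold and npl4, a cofactor of the p97 segregase in ER-associated degradation, rose 4.35-fold. The gene pdiA (DDB0232430, positions 246720 to 247623), whose symbol stands for the secreted inhibitor of cyclic nucleotide phosphodiesterase and not for a protein disulfide isomerase, fell 28.0-fold from 158 to 5.64 FPKM. The lysosomal alpha-mannosidase gene manA fell 14.0-fold and the lysozyme gene alyA 9.78-fold.

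By list, 5 of 7 listed ER chaperones rose in wild type in the authors' deposited table (dnajc3, pdi1, pdi2, cnxA and the locus that joins crtA, for calreticulin, with csn1). The 1 that fell, pdiA, was taken by the symbol pattern and is not an ER chaperone, so 0 of the other 6 fell. Of 5 listed ER-associated degradation genes 3 rose, namely npl4, derl1 (3.02-fold) and derl2 (2.57-fold), and 0 fell. Of 9 listed ER-Golgi transport genes 4 rose and 0 fell. Of 15 listed N-glycosylation genes 3 rose, the mannosyltransferases alg2 (3.76-fold) and alg11 (3.03-fold) and the phosphomannomutase pmmA (3.53-fold), and 0 fell. The median log2 changes of the ER chaperone, degradation and transport lists lay at percentiles 99.7, 99.9 and 99.3 of 10000 random lists of listed loci matched on mean expression. These medians rest on 6, 4 and 6 members with both values. The remaining listed members lacked a value for at least 1 of the groups. Of 21 listed lysosomal hydrolases 10 fell and 1, the cysteine protease cprC, rose. Of 43 listed actins and actin-binding proteins 12 fell, with act1 at 5.20-fold, abpB at 3.62-fold and fimA (fimbrin) at 3.27-fold, and 0 rose. The median of each of these lists lay below those of all its random lists (percentile 0).

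Smaller parts of other lists were called in wild type. The superoxide dismutases sodB and sodC fell 5.22- and 4.03-fold while msrA rose 2.99-fold, among 9 listed redox genes. Of 24 listed tRNA synthetases, trpS rose 3.77-fold, aspS1 rose 2.32-fold and the mitochondrial maspS fell 3.26-fold. Of 29 listed genes in the lipid and sterol list 5 fell, among them erg2 (3.94-fold) and eloB (3.21-fold), and the symbol pattern of that list also took several cytochrome P450 genes and the transcription elongation genes spt16 and spt4, so its counts are not of lipid genes alone. The autophagy receptor gene sqstm1 rose 3.05-fold and vmp1 rose 2.19-fold among 11 listed autophagy genes. One bZIP transcription factor of 16 listed members, bzpD, rose (2.95-fold). The heat shock genes hspI and hspK fell 5.77- and 3.17-fold among 20 listed cytosolic chaperones. The autocrine proliferation repressor aprA and the adhesion gene cadA fell 4.70- and 3.27-fold among 17 early development genes. The locus joining coxA fell 3.41-fold among 14 respiration genes. Among the 67 listed ribosomal protein genes, 35 DNA replication and mitosis genes, 16 proteasome genes, 9 late development genes, 5 polyketide synthases, 3 V-ATPase subunits and 2 ER translocation genes, 0 were called in the wild-type comparison in the authors' deposited table. The ribosomal list still had a median change of −0.41 in log2 of FPKM plus 1 over the 32 of 67 members with both values, at percentile 1.49 of its random lists. The others lacked a value for at least 1 of the groups, so this median does not describe the whole list.

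Among genes with symbols and a mean of at least 5 FPKM, those with the largest rises in wild type were fslF (13.1-fold, from 2.09 to 27.5 FPKM), sarB, uch1 (8.53-fold) and iliD (8.51-fold), followed by pksB (7.41-fold), the locus joining dng1 and iliB (6.05-fold), cinC (5.60-fold), abcG19 (7.75-fold) and iliC (4.73-fold) in the order of the change in log2 of FPKM plus 1. Some loci without a symbol rose more. The spliceosomal RNA locus rnu2e was listed at 0 without tunicamycin and at 6.93 FPKM with it. In the same order, among the largest falls were those of uduB (35.0-fold), ctnC (37.4-fold, from 122 to 3.26 FPKM), pdiA and the amoebapore-like gene aplN (28.5-fold), then rliF (15.0-fold), manA, stcC (13.5-fold) and gmsA (24.1-fold). ponC4 fell from 18.9 FPKM to a listed 0. In all, 607 loci were called in the authors' deposited table, 233 higher and 374 lower with tunicamycin, which is 6.18% of about 9818 loci tested. At q under 0.01 the count was 333.

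**Figure D1:**
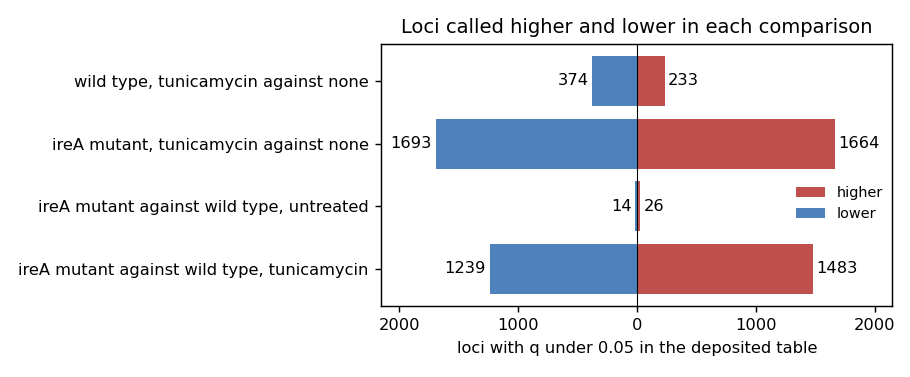
Horizontal bars give the number of loci with q under 0.05 in the authors' deposited table, higher to the right in red and lower to the left in blue, for 4 comparisons of the 4 groups. The untreated genotypes differ at 26 and 14 loci, against 1664 and 1693 for tunicamycin in the ireA mutant.

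The second comparison asked the same of the ireA mutant. Autophagy genes rose at every listed locus, ribosomal protein genes fell at every listed locus, and most listed genes of DNA replication, mitosis and the actin cytoskeleton fell. Of all 4124 listed loci 3357 were called in this comparison, 1664 higher and 1693 lower. A call at most listed members is therefore largely set by how loci came to be listed. The ubiquitin-like autophagy gene atg8 (DDB0232431, positions 4321108 to 4321704) rose 28.1-fold, from 268 to 7527 FPKM, and all 11 listed autophagy genes rose, with atg18 at 11.4-fold and atg12 at 8.78-fold. The DNA polymerase clamp pcna (DDB0232432, positions 463138 to 464515) fell 24.9-fold, from 240 to 9.65 FPKM, and 33 of 35 listed replication and mitosis genes fell, including aurK (13.9-fold), polA3 (13.1-fold) and rfc3 (14.7-fold), with the kinesin kif7 the 1 that rose. All 67 listed ribosomal protein genes fell in the authors' deposited table, with rps12 at 6.90-fold and rps20 at 6.34-fold.

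Many listed ER genes rose in the mutant as well, and others fell. sarB rose 62.1-fold from 37.7 to 2342 FPKM, dnajc3 15.2-fold, derl1 8.10-fold, pdi2 7.58-fold, npl4 7.39-fold and pdi1 6.81-fold in the authors' deposited table. Of 7 members of the ER chaperone list 4 rose, and 2 fell, grp94, the ER form of Hsp90, and pdiA (39.3-fold), which is not an ER chaperone. Of 5 listed degradation genes 4 rose, with the ubiquitin ligase amfr at 4.99-fold and cdcD, the p97 segregase, at 2.19-fold. ER-Golgi transport genes rose at 8 of 9 listed loci, with sec24l at 6.34-fold and yipf1 at 4.33-fold. Both listed ER translocation genes rose, sec63 4.90-fold and srp54 2.43-fold. N-glycosylation genes went both ways, 5 higher and 5 lower of 15, with mpi and modA higher (4.91- and 4.18-fold) and pmmB lower (8.32-fold).

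Among lysosomal hydrolases and related enzymes, the cysteine protease genes cprB and cprC rose 265- and 220-fold, from 8.83 and 3.68 FPKM. The hexosaminidase-family gene nagD rose 115-fold from 1.71 FPKM, and the fucosidase alfA 128-fold, from 7.30 to 934 FPKM. The lysosomal list was split, 5 higher and 12 lower of 21, with alyA down 47.3-fold. Among genes with symbols and a mean of at least 5 FPKM, the other leading rises were aplK (405-fold, from 1.75 to 708 FPKM, q = 0.0182), gpt7 (188-fold, from 1.01 FPKM, q = 0.00875), celB, a cellulase gene (119-fold), cfaA (84.6-fold) and dia2 (72.1-fold, from 38.7 to 2793 FPKM). With depth unknown, the size of a fold from so low a value is uncertain. The locus named tRNA-Asp-GUC-8 (DDB0232429, positions 6132169 to 6132600) went from a listed 0 to 115 FPKM. The RNA was poly(A)-selected, and which transcript gave the reads at that locus is not known here. Of 9 listed late development genes 7 rose and 0 fell, among them the non-coding developmental RNA dutA (15.8-fold), tagC and cudA (4.25-fold). Of 17 early development genes 6 rose and 6 fell, with dia2 higher and cprD (9.36-fold), ctnA (7.65-fold) and cadA (7.63-fold) lower in the authors' deposited table.

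Among the largest falls in the mutant were those of DD7-1 (120-fold, from 711 to 5.94 FPKM), wipA (82.8-fold), the ponticulin gene ponA (78.3-fold), 29C (56.8-fold), dduA (53.5-fold), alyA, pdiA, act8 (38.8-fold) and uduA3 (34.6-fold). Of 43 listed actins and actin-binding proteins 33 fell, with act4 at 34.2-fold, act16 at 18.6-fold and act7 at 18.4-fold, and 3 formin genes, forB, forC and forD, rose. Actins are a family of near-identical copies, as are the udu and hspG genes, and how reads were divided among such copies is not given in the sources used here. Of 24 listed tRNA synthetases 17 fell, the mitochondrial mileS and maspS by 13.9- and 12.2-fold, and 0 rose. Proteasome genes fell at 12 of 16 listed loci (psmD9 7.07-fold) and rose at 3, psmE4 by 3.48-fold. Of 16 bZIP and eIF2-alpha kinase genes 14 rose, with bzpN at 6.36-fold and bzpC at 5.63-fold, and 0 fell. The cytosolic chaperones split into 10 higher, led by the small heat shock genes hspG6 (9.15-fold) and hspG8 (7.67-fold), and 6 lower.

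Of the remaining lists in the mutant, 6 of 9 redox genes fell (sodC 7.57-fold, sodB 6.68-fold) and 0 rose. Respiration genes fell at 9 of 14 listed loci, with cytC at 5.05-fold and ndufab1 at 4.84-fold, and 4 loci of that list rose. By their names 2 of these, atp9b (5.73-fold) and atp7a, are P-type ATPases that the symbol pattern took and not respiration genes. The mitochondrially encoded locus atp4,atp8,cytB,nad3 was among those 4 in the authors' deposited table. In the lipid and sterol list 11 rose, led by the P450 genes cyp516B1 (39.5-fold) and cyp515B1 (9.80-fold), and 7 fell, including the sterol pathway genes mvd (5.89-fold) and hmgB (5.62-fold). Of 5 listed polyketide synthases pks5 was among 2 that rose (9.06-fold), and pks16 among 3 that fell (4.57-fold). The V-ATPase subunits vatA and vatF fell 3.25- and 2.83-fold.

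In total 3357 loci were called for tunicamycin in the mutant in the authors' deposited table, 1664 higher and 1693 lower, or 34.2% of about 9818 tested. The count was 5.53 times that in wild type. Over the 2537 loci with all 4 group values, the median change in log2 of FPKM plus 1 was 0.31 in the mutant and −0.01 in wild type, and the smallest absolute log2 fold change of any call in the table was 1.05. List medians in the mutant lay at percentile 99.6 for autophagy, 97.7 for ER chaperones, 97.6 for bZIP genes, 0.02 for replication and mitosis, 0 for actin, 1.60 for ribosomal proteins and 1.77 for tRNA synthetases. Inside the central 95% lay ER-Golgi transport at 97.2, degradation at 97.0, late development at 94.03, N-glycosylation at 53.9 and the other lists. These random lists came from 3496 loci with both values, and 3357 loci were called in this comparison. A place inside the central 95% therefore does not show that a list was unchanged.

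**Figure D2:**
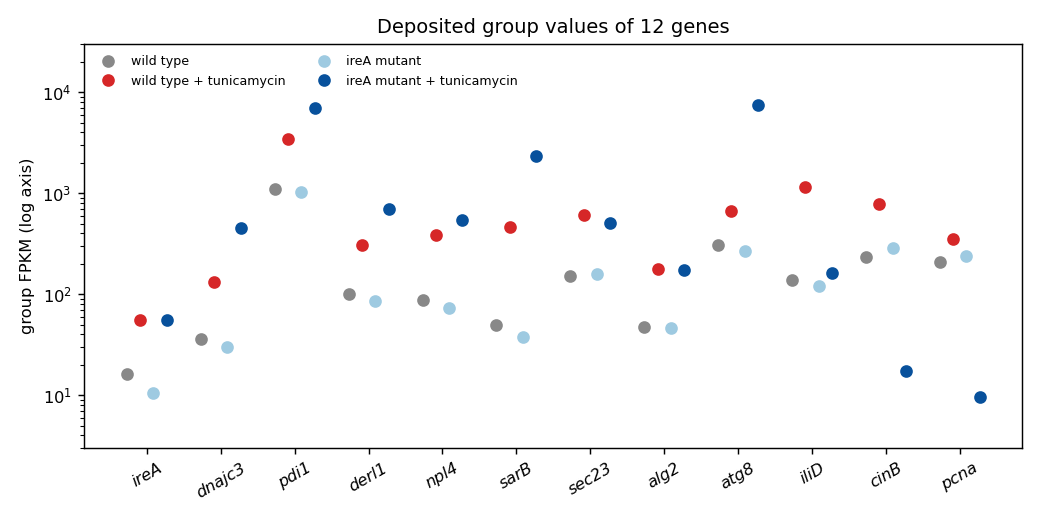
Points give the authors' value in FPKM (log axis) of 12 genes in each of the 4 groups, with no error since the table holds 1 value per group. With tunicamycin atg8 reaches 7527 FPKM and pcna 9.65 FPKM in the ireA mutant, against 664 and 354 FPKM in wild type.

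Without tunicamycin few loci were called between the genotypes. In all, 40 loci were called in the authors' deposited table, 26 higher and 14 lower in the mutant, or 0.407% of those tested, and 13 at q under 0.01. Among the genes with symbols the largest rise was that of the ponticulin-family gene ponB (DDB0232431, positions 4244481 to 4244918), 7.33-fold to 87.8 FPKM (q = 0.00239). uduD1 was 4.32-fold higher, uduA3 3.09-fold and the locus joining uduA1 and uduA2 2.74-fold, and cbpD1, a calcium-binding protein gene, cryS and cupI were 2.67-, 2.65- and 2.57-fold higher. The 3 related genes csbC, csbA and csbB were between 2.36- and 2.67-fold higher. Named by the rule among the falls were hspI (5.92-fold, q = 0.0221), tgrM2 (3.86-fold) and rtoA (3.28-fold). hspI was the 1 member of any fixed list that was called, so the ER chaperone, degradation, glycosylation, transport and autophagy lists had 0 members called between the untreated genotypes. Among list medians in log2 of FPKM plus 1, that of the cytosolic chaperones stood lowest, at −0.61 over 9 loci with both values (percentile 0). The medians were 0.16 for ribosomal proteins (percentile 100), 0.17 for replication and mitosis (99.98), 0.14 for actin (99.8) and 0.19 for early development (99.1), all above the central 95% of their random lists with 0 members called. ER chaperones had a median of −0.02 (percentile 32.3). Many loci are listed because tunicamycin changed them in the mutant, among them 67 of 67 ribosomal, 33 of 35 replication and 33 of 43 actin list members that fell. Listing for a fall favours a high untreated mutant value, and listing for a rise a low one. That group enters this comparison too, and the random lists mix rises and falls. These percentiles therefore cannot show a difference between the untreated genotypes.

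With tunicamycin present in both genotypes, the mutant differed widely from wild type. Among the largest excesses in the mutant were those of cprB (210-fold, from 11.1 to 2336 FPKM), aplK (172-fold), dia2 (156-fold), alfA (146-fold), ponB (144-fold), cigA (106-fold), nagD (87.1-fold), celB (62.6-fold) and osbA (51.5-fold). Some of these rest on low values in treated wild type, such as 2.38 FPKM for ponB, 2.18 for cigA and 2.26 for nagD. Deficits were ranked by log2 of FPKM plus 1 among genes with symbols and a mean of at least 5 FPKM. The largest by that measure were those of cinB (44.8-fold, DDB0232432, positions 5055688 to 5057020), pcna (36.7-fold), iliM (24.8-fold), DD7-1 (23.7-fold), dduA (22.3-fold), omt6 (20.1-fold), fhit (19.4-fold), the mitochondrial isocitrate dehydrogenase gene idhM (15.4-fold), abcG10 (13.1-fold) and dduF (12.9-fold). In all 2722 loci were called in the authors' deposited table, 1483 higher and 1239 lower, and 1691 at q under 0.01.

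The medians of the ER lists lay inside the central 95% of random lists, at percentile 78.2 for chaperones, 62.2 for degradation, 93.97 for transport and 44.4 for N-glycosylation, and 54.5% of all calls in this comparison were higher. The random lists came from 3027 loci with both values, while 2722 loci were called in this very comparison. The degradation median rests on 3 members. These percentiles therefore cannot show whether the ER lists differed between the treated genotypes. Of 7 members of the ER chaperone list dnajc3 (3.45-fold) and pdi2 (2.95-fold) were higher, and grp94 was lower (4.47-fold, 515 FPKM in wild type and 115 in the mutant) in the authors' deposited table. amfr (3.77-fold) and derl1 (2.27-fold) were higher among 5 degradation genes. Transport genes were higher at 5 of 9 loci (sarB 5.06-fold, golt1 4.53-fold), and sec63 was higher (4.11-fold). N-glycosylation split into 4 higher (mpi 3.82-fold, modA 3.60-fold) and 5 lower (alg6 4.51-fold). Of 11 autophagy genes 9 were higher (atg8 11.3-fold, atg18 5.80-fold), of 16 bZIP and kinase genes 11 (bzpN 4.60-fold), of 9 late development genes 7 (celB, dutA 9.80-fold, tagC 8.14-fold, and the spore coat gene cotD 7.70-fold), and in none of these 3 lists was a member lower. Early development gave 7 higher (csaA 6.49-fold, erkB 4.38-fold) and 3 lower (cprD 13.3-fold), and lysosomal hydrolases 10 higher (cprA 18.9-fold) and 6 lower.

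Most listed tRNA synthetases, replication and mitosis genes and actin list members were lower in the treated mutant than in treated wild type, with medians at percentiles 0.40, 0.01 and 0. Of the other lists only late development (99.7) had a median outside the central 95%, and ribosomal proteins lay at 8.57, over 33 of 67 members with both values. Of 24 tRNA synthetases 23 were lower (mileS 8.27-fold, ileS 5.96-fold), of 35 replication and mitosis genes 30 (rfc3 11.4-fold, aurK 10.6-fold) with 2 higher (cycD and kif7), of 67 ribosomal protein genes 31 (rps13 4.10-fold, rplP0 3.88-fold) and of 16 proteasome genes 9 (psmD9 5.33-fold) in the authors' deposited table. Of 43 actin list members 24 were lower (act8 10.8-fold, act4 10.2-fold) and 6 higher. Redox genes were lower at 6 of 9 loci (sod2 3.78-fold), cytosolic chaperones at 5 of 20 (hspA 3.01-fold) with 1 higher (hspG8 2.37-fold), and V-ATPase subunits at 2 of 3 (vatA 3.59-fold). The respiration list gave 5 lower (cox19 4.23-fold) and 4 higher, 2 of which are the P-type ATPase genes atp9b (4.24-fold) and atp7a. The lipid and sterol list gave 15 higher (cyp516B1 41.9-fold) and 7 lower (hmgB 9.22-fold, cas1, the cycloartenol synthase gene, 6.01-fold), and the polyketide list 1 higher (pks5 7.01-fold) and 3 lower (pks27 6.90-fold).

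The last comparison set the tunicamycin responses of the genotypes against each other. Of the 233 loci that rose in wild type, 118 also rose in the mutant, 20 fell and 95 were not called there. Of the 374 that fell in wild type, 249 fell in the mutant, 12 rose and 113 were not called. If the calls of both genotypes were independent among the loci tested, 39.5 loci would rise in both, 64.5 fall in both, and 40.2 and 63.4 go in opposite directions. These 2 comparisons share no library. Of the loci called in the same direction in both, the change was larger in the mutant for 93 of 118 rises and 204 of 249 falls in the authors' deposited table. At q under 0.01 in both, 58 rose in both and 132 fell in both.

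The difference of the log2 changes (FPKM plus 1, mutant minus wild type) was 7.50 for aplK, 6.89 for celB, 6.88 for cprB, 6.86 for tRNA-Asp-GUC-8, 6.43 for dia2, 5.88 for nagD, 5.83 for alfA, 5.67 for cigA and 5.45 for both cyp516B1 and osbA. It was −5.69 for cinB, −5.26 for pcna, −4.97 for iliM, −4.20 for dduA, −4.09 for abcG10, −4.07 for omt6, −3.98 for idhM, −3.97 for rsmC, −3.94 for wipA and −3.79 for act8. Values of low genes depend on the pseudocount: with 0.1 and 5 FPKM the difference was 10.17 and 4.59 for tRNA-Asp-GUC-8, which is listed at 0 in 3 groups, 6.23 and 3.87 for cyp516B1 and −4.53 and −2.76 for wipA. Of these, cinB, iliM and abcG10 rose in wild type and fell in the mutant. cinB went from 234 to 777 FPKM in wild type and from 286 to 17.3 FPKM in the mutant in the authors' deposited table. Over the 2537 loci with all 4 values, the difference was at least 1 for 1197 loci and at most −1 for 1094. Of the 3129 loci with a treated wild-type value, 2722 were called between the treated genotypes. No call lay under 1.05 in absolute log2, so these counts rest largely on how loci came to be listed. Pearson's r between the responses was 0.521 and Spearman's rho 0.610 across these loci, which are not independent replicates and were selected for having been called. At 397 loci called in both genotypes with a nonzero value in every group, an approximate z-test of the difference, added after the data were seen and resting on the standard errors implied by the authors' statistic, gave q under 0.05 for 92: 15 of 118 that rose in both, 45 of 247 that fell in both and all 32 that went in opposite directions, where 2 opposed calls all but fix the outcome. The response was larger in the mutant at 15 of those 15 and 43 of those 45. Differences at loci called in 1 genotype were not tested here.

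The loci called in wild type were also followed into the comparison of the treated genotypes. Of the 233 loci raised by tunicamycin in wild type, 87 were lower in the mutant with tunicamycin than in wild type with tunicamycin and 45 were higher, in the authors' deposited table. Among the 87, 65 were not called for tunicamycin in the mutant. iliD rose from 137 to 1164 FPKM in wild type and stood at 120 and 161 FPKM in the mutant, and the locus joining dng1 and iliB stood at 185 FPKM in treated wild type and 39.1 in the treated mutant. These 2 comparisons share the treated wild-type libraries. Of the 374 loci lowered in wild type, 77 were higher in the treated mutant and 94 lower, and 54 of the 77 were not called for tunicamycin in the mutant. Simulated loci with no effect gave 4.31 overlaps of the kind that opposes the wild-type change for either set, and independent lists would give 29.4 for the raised and 56.5 for the lowered loci. The simulation had no effect in any group, and the independent lists leave out the shared libraries. Neither number covers real effects and shared libraries together, so neither sets the number to expect here. Overlaps in the direction of the wild-type change, which the shared libraries disfavour, would number 35.2 and 47.2 in independent lists, against the 45 and 94 found, so that for the lowered loci these exceed their number by more than the opposing ones do.

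**Figure D3:**
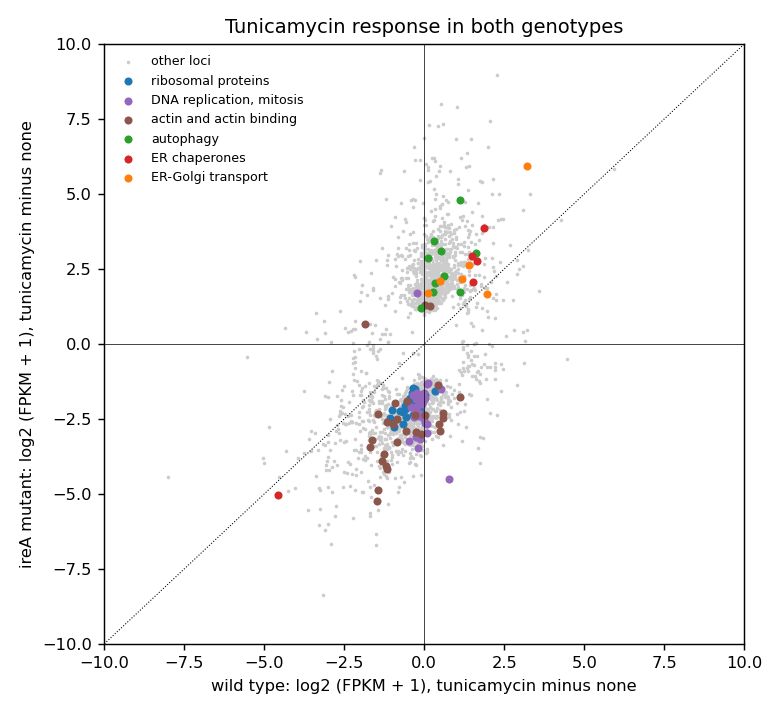
Each point is 1 of the 2537 loci with all 4 group values, with the change in log2 of FPKM plus 1 under tunicamycin in wild type on the x axis and in the ireA mutant on the y axis, and members of 6 fixed lists are coloured. Loci are listed only where some comparison called them, which leaves a gap near 0 on the y axis, and the SD of the changes is 1.05 in wild type and 2.53 in the mutant.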

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

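The tests of explanations and the z-test in this part were chosen after the results were seen, while the overlaps of calls were planned before. The differences between the genotypes' responses given here had q under 0.05 in an approximate z-test from the standard errors implied by the authors' statistic, which opposed calls all but fix. They stand out because the groups' values move in opposite directions. With tunicamycin 20 loci rose in wild type and fell in the ireA mutant, and 12 fell in wild type and rose in the mutant, in the authors' deposited table. Among genes named by rule, the difference of the log2 responses was −5.69 for cinB, −4.97 for iliM and −4.09 for abcG10. Others in the first set are the vault protein gene mvpA (333 to 728 FPKM in wild type, 363 to 112 in the mutant), ddiA (286 to 754, and 273 to 85.2) and cnrK, and in the second the homeobox gene hbx2, arrJ and arrK (43.9 to 10.4, and 39.2 to 131). These were named after their values were seen.

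The first pattern is the larger number of loci called with tunicamycin in the mutant than in wild type. Scaling by a few abundant genes acts as 1 factor for all other loci, so it would enlarge rises and shrink falls, or the reverse. Instead, among loci called in the same direction in both genotypes, 78.8% of the rises and 81.9% of the falls were larger in the mutant. Sizes here are changes in log2 of FPKM plus 1. A less precise wild-type comparison would leave the sizes alike or, as these loci had to pass in both genotypes, favour larger wild-type changes. Instead, 80.9% of those 367 loci changed more in the mutant. At the 397 loci called in both with a statistic, the median ratio of implied standard errors, mutant over wild type, was 1.001 (quartiles 0.929 and 1.084). Loci called in only 1 genotype are not covered by this ratio. A single deviating library in the treated mutant group stays open, because the table holds 0 replicate values, and it cannot be told apart from an effect of ireA. Lower growth or survival of the treated mutant cells also stays open and was not measured here.

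The second pattern is the ireA signal in the mutant, which reached 56.2 FPKM with tunicamycin against 55.3 in wild type. If wild-type cells in the same state had stood in for the treated mutant, few loci would differ between the treated groups, whereas 2722 were called. A deviating library or lower growth or survival, left open above, could also give many calls. The count therefore cannot decide whether wild-type cells were present, in whole or in part. Reads from an undisrupted part of the locus may give the 5.29-fold rise in the mutant, and this cannot be told apart from an intact gene with 1 value per locus. An exchange of the names of the treated groups would leave the signal, since the treated mutant would then stand at 55.3 FPKM. Of the 40 loci called between the untreated genotypes, 16 were called in the same direction between the treated genotypes and 8 in the opposite one. Among them 6 had no tunicamycin call in either genotype under the names as given, and 0 kept their direction without such a call under exchanged names.

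The loci that moved in opposite directions were fewer than independent calls in the genotypes would give, 40.2 and 63.4 against the 20 and 12 found, and 7 and 1 were left at q under 0.01 in both. No explanation of them was tested.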

How the results depend on the processing

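Of these alternatives, single-gene loci, centring and lists without members of other functions were chosen after the data were seen, and the others before. The counts of called loci in the 4 comparisons stayed within 1.5 times under a 2-fold minimum (which removed 0 loci, so that it tests nothing), at least 1 or 10 FPKM in 1 of the groups, and single-gene loci. At q under 0.01 fewer loci pass by construction: 333 for tunicamycin in wild type, 13 between the untreated genotypes and 1691 between the treated genotypes, against 607, 40 and 2722, while 2278 of 3357 were left for tunicamycin in the mutant. At that threshold 28 of 78 counts of called list members and 10 of 14 counts by direction moved by more than 1.5 times, as did 4 of 78 list counts with at least 10 FPKM. The overlaps at q under 0.01 were 58 higher in both, 132 lower in both, 7 higher in wild type and lower in the mutant and 1 the other way, against 118, 249, 20 and 12. Pseudocounts of 0.1 and 5 gave 1211 and 1091 loci with a difference of responses of at least 1, and 1117 and 968 at most −1. Of the 20 named differences 3 moved by more than 1.5 times in fold with 0.1 and 10 with 5, and 0 changed sign. Centring on the median left all counts of higher and lower loci within 1.5 times. The largest median was 0.373, while no call lay under 1.05 in absolute log2. No direction could therefore change, and centring tests nothing either. The number of lists outside the central 95% was 6, 7, 5 and 4 in the 4 comparisons in the order of the text up to the treated genotypes, 8, 8, 5 and 4 with unmatched lists and 6, 6, 6 and 4 with members of at least 10 FPKM. Without pdiA, atp7a, atp9b, spt16 and spt4 it was 6, 7, 5 and 4, and 4 of 16 counts of the lists concerned moved by more than 1.5 times: ER chaperones lower with tunicamycin, from 1 to 0 in wild type and from 2 to 1 in the mutant, and respiration genes higher, from 4 to 2 in the mutant and between the treated genotypes. Of 253 named gene results 33 had q of 0.01 or more, and 6 lay under 10 FPKM in both groups. No paired analysis was possible because the columns carry no replicate. Leaving out libraries, other scalings of libraries, other replicate tests, fits of only the groups compared, the pseudocount within a test and estimated correlations were not run for the same reason. Depth is unknown, so its limits on low genes could not be set.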

Other observations

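The tests in this part were chosen after the results were seen. Some gene families outside the fixed lists moved mostly one way in the mutant with tunicamycin, and others did not. All 17 called vps genes, most of them for vacuolar sorting and membrane remodelling, rose (Fisher's exact test of direction, two-sided, against other called loci, adjusted p = 4.32e-05 over 41 family tests), as did all 12 called rab genes, for small GTPases of vesicle traffic (adjusted p = 0.000737). All 12 called loci marked as retrotransposable elements rose (adjusted p = 0.000737), and 19 of 20 were higher in the treated mutant than in treated wild type (adjusted p = 0.00067). These are repeated sequences, and how their reads were divided is not given in the sources used here. All 13 called ddx genes, for DEAD-box RNA helicases, fell (adjusted p = 0.000757), as did all 8 called cup genes (adjusted p = 0.0145) and 9 of 10 called grl genes, for receptors of the glutamate and GABA type (adjusted p = 0.0365). Others went both ways, with 10 higher and 13 lower abc transporter genes, 5 and 5 gta genes, 4 and 5 gef genes, 3 and 7 apl genes, 9 and 4 gxc genes, 7 and 3 tmem genes and 2 and 6 mcf genes. Genes are not independent replicates, and related copies share reads, so these p-values describe the table and are too small.

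Of the ili genes in wild type, 7 of 8 called members rose with tunicamycin (adjusted p = 0.0122), and 8 of 8 called members were lower in the treated mutant than in treated wild type (adjusted p = 0.00439), in the authors' deposited table. The 2 sets differ by 1 member each, iliG and iliP. These comparisons share the treated wild-type libraries, and no test of this family was run for tunicamycin in the mutant.

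Lower growth-related transcripts and higher autophagy transcripts in the treated mutant may reflect a starvation-like state, as a hypothesis. It would need the early development list, which was fixed to hold genes of early development and starvation, to rise, and 50.0% of its 12 called members did. Members of other functions were not taken out of that list, and its members cprD and cprE are also in the lysosomal list. The share therefore cannot decide the question, which remains open. dutA and 6 other late development genes rose, and the abundant early gene cadA fell from 15513 to 2033 FPKM in the mutant with tunicamycin.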
